A study of Mus musculus with 4 samples.

How the data were processed

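Single-cell 3' RNA profiles of sorted thymic Treg cells were analysed from 4 samples, 1 for each of the wild type and the knockout of an Il2 line and an Il15 line. The first table holds deposited UMI counts, whole numbers for 27998 genes in 8273 cells. Per the submitters' processing notes, CASAVA 2.20, Cell Ranger 2.0.2, R 3.4.1 and the mm10 build were used, and the cell filter is not given in the sources used here. The second table holds log2 values that the authors deposited for 9571 genes in 7231 cells, named as G1 cells. Tested against the counts, each value was the log2 of the count divided by 1 factor per cell, plus 1 (largest relative deviation 1.1e-14, factors 0.168 to 5.68, median 0.768). How the factors, the phase of each cell and the gene filter were set is not given in the sources used here. Gene symbols were given to 27645 identifiers from the GENCODE M21 annotation of GRCm38, and 353 identifiers had none.

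Columns are barcodes with a suffix from 1 to 4, taken as 4 libraries. No label gives the sample behind a suffix, and all 8273 columns were left unassigned. The comparisons of each knockout with its wild type, fixed before the values were seen, were therefore not run, and no genotype was inferred from Il2, Il15 or any other value. Depth was 795 to 32737 UMIs and 362 to 4861 genes per cell. Scrublet predicted 44 doublets (0.532%), fewer than loading such numbers of cells usually gives, so its calls were used only as an alternative.

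Clusters were made with scanpy 1.11.5 from counts scaled to 10000 per cell and logged, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.6 (igraph 0.11.9), and no integration. Receptor segment, sex-linked, ribosomal protein, mitochondrial, S phase and G2 and M phase genes were left out of the variable genes. A cluster took the name of a marker class fixed beforehand when 3 or more, and at least 50% by number, of its detected markers were 1.5-fold higher and at least 1 was among its 10 leading genes. This naming rule, the comparison of each cluster with all other cells, the stratification by library and the rule for a called gene were set after the data were seen.

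The ratio of CPM between a cluster and all other cells was the Mantel-Haenszel ratio over all 4 libraries, with 0.5 UMIs added for the log. It had an approximate 95% counting interval. Directions within a library were taken only where it had at least 20 cells on each side. The CPM printed beside it are plain sums over libraries, so their quotient can differ from the ratio. Cells are not replicates, and no p-value was computed. The 24 gene lists were fixed beforehand, and 4 of their genes were not analysed here. List members needed 50 UMIs and a list 4 members, which left 19 lists in the 10 contrasts. The median log2 ratio was placed among 10000 random lists of the same size matched in 20 expression bins, and called outside below percentile 2.5 or above 97.5. Genes are named as follows: up to 12 with the largest ratio each way among called genes, up to 4 members per list, and the cytokine, receptor, Foxp3, Bcl2, Cd4 and Cd8a genes in each library.

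Shares have exact Clopper-Pearson intervals and CPM exact Poisson intervals. In thinning, 1811 UMIs were drawn from each cell with at least that many, the 10th percentile, which kept 7447 cells. The contrast was tested on simulated data for cluster 4 against all other cells over 8067 genes. Simulated counts were Poisson draws from each library's summed profile, with the same change in every library. The rates that follow therefore cover counting error only, and uneven counts between cells were not simulated. It recovered 27 of 50 genes changed 1.5-fold (54%), 69 of 75 changed 2-fold (92%) and 71 of 75 changed 3-fold (94.7%), called 0.42% of unchanged genes, and 95.5% of its intervals held the true value. Alternatives covered scaling (median of ratios, trimmed mean of M-values, totals without mitochondrial and ribosomal protein genes), cell filters (at least 500 genes and at most 10% mitochondrial UMIs, no doublets, no proliferating cells, no double-positive-like cluster), weighting, thinning, expression bins, the normalized table, clustering settings and leaving out each library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.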

Results

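The series profiled regulatory T (Treg) cells, the CD4 T cells that restrain immune responses, from the thymus of 3-week-old mice. Per the labels, cells were sorted as CD4+CD8-Thy1.1+GFP+ from animals in which Foxp3, the transcription factor that defines Treg cells, drives a Thy1.1 surface reporter. GFP from Rag2 regulatory sequence marks recently formed T cells. The 4 samples were 1 wild type and 1 knockout for Il2, and 1 wild type and 1 knockout for Il15, each captured as single cells with a droplet 3' kit that counts unique molecular identifiers (UMIs). The stated question was how much, and in what way, IL-2 and IL-15 shape the development, selection and differentiation of Treg cells. The count table held 8273 cells and 27998 genes. Barcodes ended in 1 of 4 suffixes, taken here as 4 libraries of 1609, 2452, 2037 and 2175 cells, with total counts of 7890384, 11274713, 5717732 and 8349421 UMIs. The median cell had 3857, 3640, 2501 and 3019 UMIs in libraries 1 to 4.

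No label tied a suffix to a genotype, so libraries 1 to 4 are unassigned and no knockout was compared with a wild type. The targeted genes were counted in every library first. Il2 (chromosome 3, 37120523 to 37125959, GRCm38), which encodes the T cell growth factor IL-2, gave 294, 340, 244 and 306 UMIs, or 37.3, 30.2, 42.7 and 36.6 counts per 1000000 UMIs (CPM). No library lacked Il2 UMIs, and these 3' tags cannot show whether the coding sequence was intact. Across the 6 clusters with over 400 cells (below), Il2 pooled over libraries lay between 27.2 CPM in cluster 4 and 42.1 CPM in cluster 1. The order of clusters differed within libraries: in library 1, cluster 1 had 34.7 CPM and cluster 6 had 44.7 CPM. Il15 (chromosome 8, 82331632 to 82403222) gave 8, 5, 1 and 2 UMIs, too few to tell libraries apart. Neither gene therefore checks the labels. Foxp3 was low in all 4 libraries, between 12.6 and 14.3 CPM, while Cd4 lay between 134 and 161 CPM and Cd8a between 10.3 and 22 CPM.

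The comparisons that could be made were between cell states across the 4 libraries. Clustering gave 9 clusters of 2908, 2089, 1121, 672, 587, 469, 239, 98 and 90 cells, and 5 met the marker rule for a name. Each cluster was compared with all other cells by the ratio of CPM, stratified by library. Intervals are 95% and cover counting error only, and with 1 library per genotype there is no replicate test. A list member is called higher or lower when it had at least 200 UMIs, differed at least 1.5-fold with an interval off zero change, and moved the same way in every library with at least 20 cells on each side. A list is called above or below when its median log2 ratio lay outside the central 95% of 10000 random lists matched on expression. Such calls were common: 15, 14, 13, 13, 17, 12, 8, 13 and 10 of the 19 lists lay outside in clusters 1 to 9. Random lists were drawn gene by gene, so a list whose genes vary together falls outside more readily. Of 8071 genes tested, 513 (cluster 3) to 1965 (cluster 6) were called higher or lower. Leaving out 1 library took Tmie, Itgb3, Irf4, Ccr8, Il1r2, Lag3, Lgals3, Nefh and S100a6 under 200 UMIs and so ended their calls, with ratios still at least 3.73-fold. Many list genes also took part in the clustering, so these values describe what sets the clusters apart and are not independent evidence. Lists also share genes with each other and with the naming markers, so a list that goes with a cluster's name partly restates it. Rag1, Dntt and Cd8a are in both the double-positive and immature thymocyte lists, and Il2ra and Socs2 in both the IL-2 and STAT5 and Treg identity lists.

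**Figure D1:**
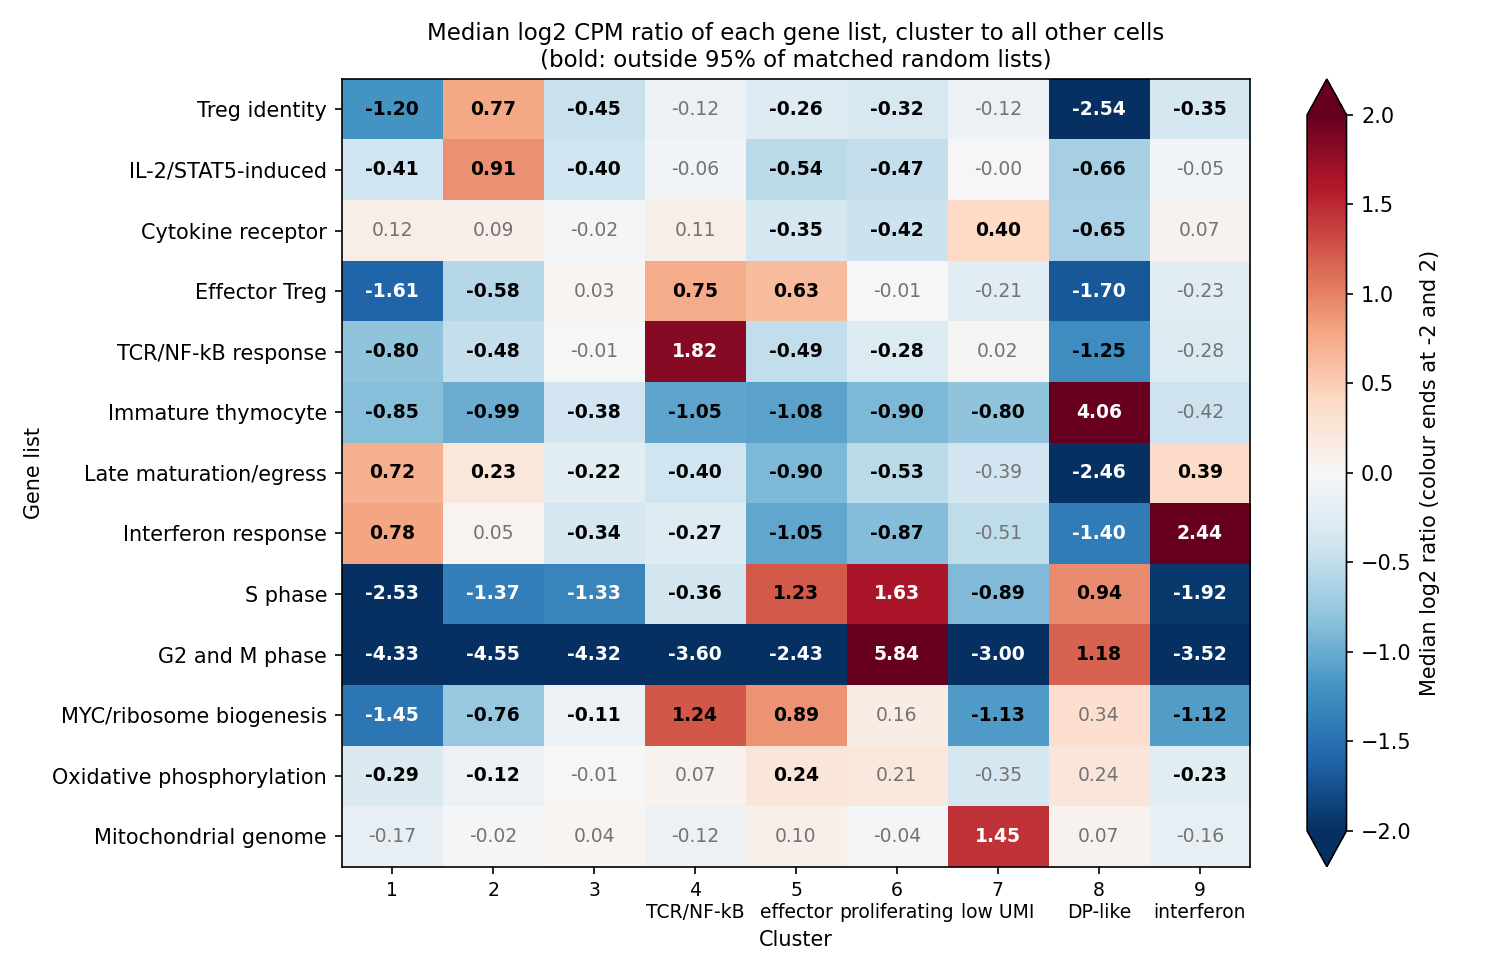
Median log2 CPM ratio of 13 gene lists (rows) in each of the 9 clusters (columns) against all other cells, with bold values outside the central 95% of matched random lists. The largest value is the G2 and M phase list in cluster 6, at 5.84, and the TCR and NF-kB response list is above in cluster 4 alone, at 1.82.

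Cluster 1, the largest state, carried late maturation, egress and interferon genes and had low Treg identity and biosynthesis genes. Of 18 late maturation and egress genes, 9 were higher and none was lower (median log2 ratio 0.72). Ly6c1 stood at 46.0 against 8.35 CPM (3.92-fold stratified by library), S1pr1, the receptor that guides T cells out of the thymus, at 334 against 145 CPM, and Gimap4 at 989 against 397 CPM. Of 20 interferon response genes, 13 were higher and none lower (median 0.78), including Iigp1 (2.79-fold stratified by library) and Gbp2 (2.10-fold). Markers of conventional naive CD4 cells were also above (6 of 8 higher, 1 lower, median 0.80), with Satb1, a chromatin organiser, at 711 against 297 CPM and Lef1 at 444 against 246 CPM. Satb1 and Ccr9 of this list are also immature thymocyte genes, a list that was below (3 of 15 higher, 4 lower, median -0.85). Its median was 0.20, -0.02, -1.64 and -0.94 in libraries 1 to 4. Genes known to be induced by IL-2 and STAT5 were below (4 of 18 higher, 7 lower, median -0.41), with a median of 0.01 in library 3. Among 16 Treg identity genes, 9 were lower and none was higher (median -1.20), with Il2ra, the IL-2 receptor alpha chain, at 33.0 against 183 CPM and Tnfrsf9 at 71.2 against 330 CPM. MYC target and ribosome biogenesis genes were lower in 19 of 20 cases (median -1.45), among them Srm and Odc1 of polyamine synthesis. TCR and NF-kB response genes were lower in 15 of 21 cases (median -0.80), and effector Treg genes in 9 of 13 cases, with 1 higher (median -1.61). The 9 effector genes became 5 without library 1 and 4 without library 2, and the effector median was -0.99 with clusters made without list genes. Genes that led the ratios were Tmie (5.42-fold, 8.76-fold without library 3), Itgb3 (4.44-fold) and Tdrp (4.17-fold), and those at the other end were cell cycle genes such as Nusap1, at 1.61 against 94.5 CPM. With all list genes kept out of clustering, the best matching cluster no longer had low Treg identity genes (median 0.09, percentile 78.8). That joint cluster of 3201 cells held 1765 cells of cluster 1 and 1248 of cluster 2. In the same clustering the interferon median was 0.28, still above, with 0 members called higher. Without proliferating cells 7 interferon genes were called higher.

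Cluster 2 carried the genes of IL-2 receptor signalling and Treg identity. Of 18 genes known to be induced by IL-2 and STAT5, 9 were higher and none was lower (median log2 ratio 0.91). Socs2, a feedback inhibitor of cytokine signalling, was at 81.7 against 14.3 CPM (log2 ratio 2.16, 1.98 to 2.34), Cish at 188 against 78.8 CPM, Lta at 103 against 39.1 CPM and Osm at 25.1 against 10.4 CPM. Of 16 Treg identity genes, 9 were higher and 1 was lower (median 0.77), with Gpr83 at 331 against 96.8 CPM, Lrrc32 at 123 against 45.4 CPM and Il2ra at 265 against 107 CPM (log2 ratio 1.04, 0.96 to 1.12). Il2rb, the beta chain that IL-2 and IL-15 receptors share, was at 351 against 137 CPM and 2.48-fold higher. The common gamma chain Il2rg had a log2 ratio, stratified by library, of -0.09 (-0.16 to -0.02) in cluster 2, and the anti-apoptotic gene Bcl2 one of 0.94 (0.90 to 0.98). Other leading genes were Drc1 (3.25-fold), Gata1 (3.07-fold), Grifin (3.05-fold) and Rgs1, at 439 against 134 CPM. TCR and NF-kB response genes were below (7 of 21 lower, none higher, median -0.48). As in cluster 1, the late maturation and egress list was above (2 of 18 higher, 1 lower, median 0.23). MYC target genes (15 of 20 lower, none higher, median -0.76) and effector Treg genes (4 of 13 lower, 1 higher, median -0.58) were below, also as in cluster 1. Cluster 2 had no counterpart of its own once list genes were kept out of clustering: its best match was the joint cluster named above, where the IL-2 and STAT5 list stayed above (median 0.35, percentile 99.9) and the Treg identity list did not (0.09).

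**Figure D2:**
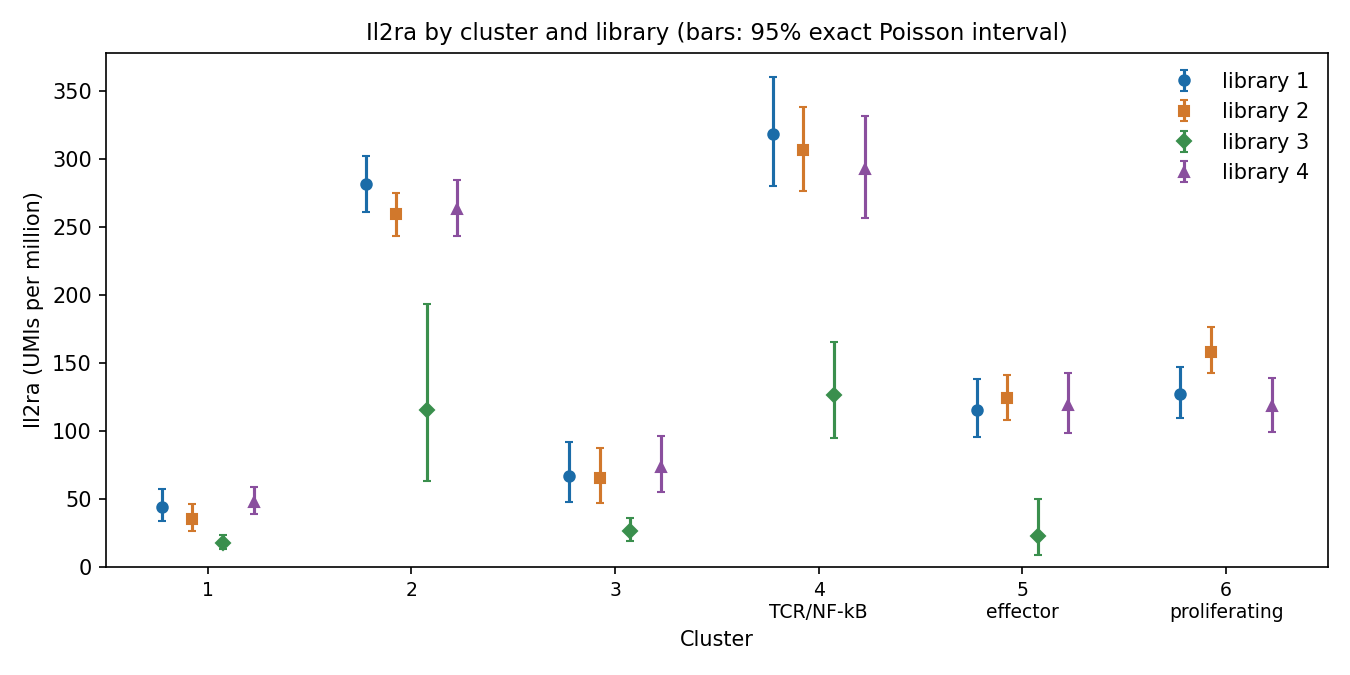
Il2ra level (vertical axis, CPM) in clusters 1 to 6 (horizontal axis) for each unassigned library with at least 20 cells, with exact Poisson 95% intervals. Clusters 2 and 4 have the highest pooled levels, 265 and 282 CPM, and cluster 1 the lowest, 33.0 CPM.

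Cluster 3 had lower levels of IL-2-linked transcripts. Of 18 IL-2 and STAT5 genes, 6 were lower and none was higher (median -0.40), with Pim1 at 79.5 against 208 CPM and Il2ra at 49.2 against 162 CPM. Of the Treg identity genes, 2 were higher and 2 lower (median -0.45), and the median was -0.60, -0.33, 0.35 and -0.47 in libraries 1 to 4, with the opposite sign in library 3. Without library 3, 8 Treg identity genes were lower and 1 IL-2 and STAT5 gene was higher. Tnfrsf9, a costimulatory receptor, was at 501 against 244 CPM and Gpr83 at 65.4 against 172 CPM. Genes that led the ratios included Nrp2 (3.70-fold), Igsf3 (2.84-fold), Rgs16, at 88.0 against 37.1 CPM, and Lmo4, at 454 against 181 CPM. Among markers of other cell types, Cd74, the invariant chain of MHC class II, was at 143 against 62.1 CPM and called higher. Krt8, an epithelial keratin, gave 19 UMIs here and 12 elsewhere, and H2-Aa 12 and 36, too few for a call. None of the 19 measured lists was above in this cluster.

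Cluster 4 met the rule for TCR and NF-kB-signalled Treg-like cells, with all 12 detected markers at least 1.5-fold higher. TCR and NF-kB response genes were higher in 19 of 21 cases (median 1.82). Nr4a3 was at 85.0 against 6.85 CPM, Egr2 at 73.5 against 7.59 CPM, Irf4 at 38.4 against 3.54 CPM and Cd83 at 315 against 40.8 CPM. The chemokine gene Xcl1 led the ratios (14.5-fold, 23.1-fold without library 1), and other high ratios were those of Nr4a3 (12.5-fold), Gadd45b (9.24-fold), Gpr183 (8.50-fold) and the anti-apoptotic Bcl2l1, at 276 against 33.6 CPM. MYC target and ribosome biogenesis genes were higher in 17 of 20 cases (median 1.24), including Srm at 227 against 49.6 CPM and Nolc1 at 179 against 50.8 CPM. Among 13 effector Treg genes, 6 were higher (median 0.75), among them Ccr8, Batf and Rora. Among 18 egress genes, 6 were lower (median -0.40), with S1pr1 at 47.8 against 203 CPM and Klf2, its transcriptional activator, at 529 against 1330 CPM. The 4 measured markers of NK, NKT and gamma delta T cells were also above (2 higher, median 1.13), with Nkg7 at 391 against 111 CPM besides Xcl1. In the clustering without list genes the MYC list median was 0.46 with 9 members higher, the egress list median 0.04 (percentile 80.8) and the NK, NKT and gamma delta median 0.01 (percentile 60.3), so the last 2 calls ended there.

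Cluster 5 met the rule for effector Treg-like cells on 9 of 15 detected markers, and no cluster met that rule when library 2, 3 or 4 was left out. Of 13 effector Treg genes, 6 were higher and none lower (median 0.63), with Il1r2, a decoy receptor for IL-1, at 25.4 against 5.31 CPM and Lag3 at 27.2 against 7.23 CPM, besides Ccr6 and Itgb8. The median was 1.13 when each cell was counted alike, and 3 members were higher without library 2. S100a6 (9.05-fold) and Lgals3 (7.36-fold, 12.7-fold without library 2) led the ratios. Markers of NK, NKT and gamma delta T cells were above as well (2 of 4 higher, median 0.79; 1.96 without proliferating cells, 1.54 with each cell counted alike and 1.83 with clusters made without list genes), with Nkg7 at 377 against 106 CPM and Ccl5 at 113 against 32.8 CPM. The erythroid list (median 9.43, 0 members called) rests on 1 cell, which held 10398 of the 10412 haemoglobin UMIs of the cluster. Foxp3 was called lower, at 6.42 against 14.2 CPM. Treg identity genes were below (1 higher, 5 lower, median -0.26, percentile 1.87), but that call ended without library 1 (percentile 3.28) or library 2 (percentile 7.29), and the median was 0.07 with clusters made without list genes. Genes of S phase were higher in 14 of 18 cases (median 1.23), including Ung at 172 against 24.9 CPM and Mcm3 at 218 against 58.8 CPM. The G2 and M phase list was below (5 of 17 lower, none higher, median -2.43), with a median of 0.43 in library 3. MYC target genes were higher in 18 of 20 cases (median 0.89). Interferon response genes were lower in 18 of 20 cases (median -1.05), with Ifit1 at 42.5 against 154 CPM, and egress genes in 11 of 18 cases (median -0.90), with Gimap4 at 175 against 579 CPM. Of the IL-2 and STAT5 genes 7 were lower (median -0.54), led by Bcl2 at 325 against 644 CPM, but in the clustering without list genes that median was -0.02 (percentile 46.4). The S phase median was 0.59 there.

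Cluster 6 was the proliferating cluster, with 11 of 11 markers and a median of 9584 UMIs per cell. All 17 G2 and M phase genes were higher (median 5.84), with Ube2c at 769 against 7.68 CPM and Nusap1 at 485 against 5.37 CPM, and 17 of 18 S phase genes were (median 1.63). Interferon response genes were lower in 18 of 20 cases (median -0.87). Directions in this contrast were checked in libraries 1, 2 and 4 only, because library 3 had 5 cells in the cluster. Those cells still entered the ratios. The authors' second table, of normalized values, holds 7231 cells of the G1 phase according to its name. Of the 1042 cells left out of it, 384 were in cluster 6, which is 81.9% of that cluster. Cells left out had G2 and M phase genes above (17 of 17 higher, median 4.88) and S phase genes above (14 of 18 higher, 1 lower, median 1.09). Transcripts of the mitochondrial genome were also above in them (median 0.35, no member called higher), and that median was 1.08 without proliferating cells. Double-positive thymocyte markers were above too (2 of 9 higher, median 1.13), with a median of -1.09 in library 1 and 0.45 to 2.35 in the others. Members called higher numbered 4 without library 1 and 1 without library 2, 3 or 4, and the median was 0.72 without library 3. Without cluster 8 this median was 0.10 (percentile 71.4). Without proliferating cells, which are defined by the G2 and M phase list itself, that list had a median of 0.08 (percentile 46), the S phase median 0.26 (percentile 93.5) and the interferon median was -0.11 (percentile 54.4).

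Of the small clusters, cluster 8 was double-positive thymocyte-like, an earlier stage that bears both CD4 and CD8. The CD8- sort gate should remove such cells. By the naming rule, 9 of 10 double-positive markers and 10 of 11 markers of proliferating cells were at least 1.5-fold higher. By the rule for list members, 6 of 9 double-positive markers were higher (median 7.49). The S phase (5 of 18 higher, median 0.94) and G2 and M phase lists (1 of 17 higher, median 1.18) were above. In libraries 2, 3 and 4 the S phase median was -0.16, 2.94 and 0.29 and the G2 and M phase median -1.38, 4.81 and 1.63. Without library 3 the S phase and G2 and M phase medians were 0.02 and 0.40, no longer above, and without library 2 they were 1.38 and 1.97, with 10 and 16 members higher. Dntt, which adds nucleotides to antigen receptor junctions, was at 1100 against 1.70 CPM (522-fold, 930-fold without library 3) and Cd8a at 971 against 5.59 CPM. Among 15 immature thymocyte genes, 10 were higher (median 4.06), and Treg identity genes were lower in 10 of 16 cases (median -2.54). Foxp3 gave 0 UMIs in 334842, which allows up to 11 CPM (exact Poisson). Cluster 9 was interferon-response Treg-like on 11 of 11 markers, with 19 of 20 interferon genes higher (median 2.44). Ifit3 was at 1010 against 41.5 CPM, Isg15 at 2150 against 180 CPM and Rsad2 37.2-fold higher, while 13 of 20 MYC target genes were lower (median -1.12). That number was 8 without library 2, and 5 without proliferating cells, where the median was -0.70. Egress genes were above in cluster 9 as well (5 of 18 higher, median 0.39). Cluster 7, of 239 cells, stayed unnamed: its median cell had 1470 UMIs, 12 of 13 mitochondrial transcripts were higher (median 1.45), and 82% of its cells were left out of the normalized table. It had no counterpart in the clustering without list genes (best Jaccard index 0.0892), where the mitochondrial median was 0.19 with 0 members called higher.

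**Figure D3:**
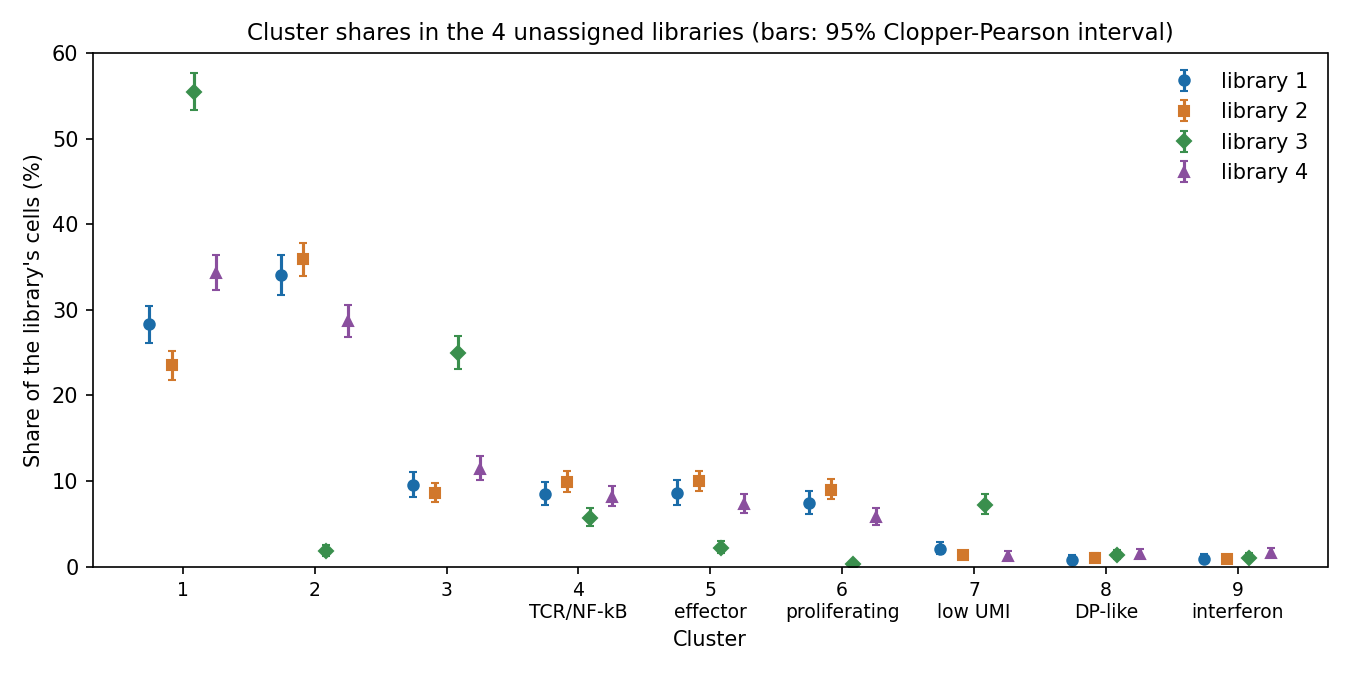
Share of each library's cells (vertical axis, percent) in the 9 clusters (horizontal axis) for the 4 unassigned libraries, with exact Clopper-Pearson 95% intervals. Cluster 2 ranges from 1.82% in library 3 to 35.9% in library 2, and cluster 1 from 23.5% in library 2 to 55.5% in library 3.

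Pooled over all cells, the TCR and NF-kB-signalled class made up 8.12% of cells (7.54 to 8.73, Clopper-Pearson), the effector class 7.1% (6.55 to 7.67), the proliferating cluster 5.67% (5.18 to 6.19), the double-positive class 1.18% (0.963 to 1.44) and the interferon class 1.09% (0.876 to 1.34). These shares depend on the clustering, and the effector class ran from 1.89% to 43.2% over other resolutions. Across the 4 libraries the median share was 31.3% for cluster 1, 31.4% for cluster 2 and 10.5% for cluster 3. By a count that needs no clusters, 22.6% of cells (21.7 to 23.5) had at least 3 UMIs of G2 and M phase genes. Per library this was 29.5%, 31.4%, 6.33% and 22.6%. With every cell thinned to 1811 UMIs, which leaves out 52, 135, 415 and 224 cells, the shares were 13.3%, 15.5%, 2.77% and 11.4%. The double-positive marker list summed to 107.2, 115.8, 171.7 and 176.3 CPM, which can include free RNA as well as captured cells.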

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

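Stratifying by library, the unstratified sums, the clustering without list genes, leaving out a library and reclustering thinned or doublet-free cells were chosen after seeing the data. So were 6 further lists (NK, NKT and gamma delta in clusters 4 and 5, Treg identity in cluster 5, both cell cycle lists in cluster 8, double-positive in cells left out). So were the cluster contrasts, their rule for a called gene and the lists tried in each. Other alternatives were set beforehand. Of 44 list medians under 767 alternatives, 742 kept their direction and their side of the random lists. Under every alternative 31 medians did so. Scaling, nearly the same for all genes, and dropping 44 doublets could hardly change sides, and each kept all 44. All 44 lay outside in the main setting, so lists inside are not covered. For the exceptions, the cause was not tested except where stated. With clusters made without list genes, the Treg identity median turned to 0.09 for cluster 1 and shrank to 0.09 for cluster 2, the egress median of cluster 4 turned to 0.04, its NK, NKT and gamma delta median shrank to 0.01, and the IL-2 and STAT5 median of cluster 5 was -0.02. Without proliferating cells, the medians of cells left out of the normalized table were 0.08 for G2 and M phase, 0.26 for S phase and -0.11 for interferon; the first follows from how those cells are defined. In the normalized G1 table the MYC median of cluster 7 was -0.12, with 82% of its cells absent. The Treg identity median of cluster 5, -0.26, was 0.07 with clusters made without list genes, 0.01 in the normalized table, -0.12 with each cell counted alike, -0.24 thinned, -0.26 in 10 expression bins, -0.14 with members of 200 UMIs, -0.17 unstratified and -0.31 to -0.18 leaving out a library. For cluster 8 the S phase median, 0.94, was 0.78 thinned, 0.02 in the normalized table and 0.02 to 1.38 leaving out a library, and the G2 and M phase median, 1.18, was 0.41 without proliferating cells and 0.40 to 1.97 leaving out a library. The double-positive median of cells left out, 1.13, was 0.51 without proliferating cells and 0.10 without cluster 8. Leaving out a library left all other medians on their side, though numbers of called members changed. Without library 3 the mitochondrial median of cells left out went from 0.35 to 0.23, and their double-positive median to 0.72.

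Class shares were unstable (adjusted Rand index between clusterings 0.28 to 0.66). The effector share of 7.1% became 43.2% at resolution 0.3, 1.89% at resolution 1.0, 11.1% with stricter cells, 2.34% thinned, 14.3% without doublets and 19.7% without list genes. It was 20.7% without library 1, and no cluster met its rule without library 2, 3 or 4. The TCR and NF-kB share of 8.12% became 9.6% at resolution 1.0, 8.97% with stricter cells, 6.61% without doublets, 5.57% without list genes and 4.01% to 12.6% on leaving out a library. The interferon share of 1.09% became 7.59% at resolution 1.0, 11.3% thinned, 2.83% without list genes and, leaving out a library, 1.04% to 10.6%. At resolution 0.3 no cluster met the rule for either class, nor for the interferon class without doublets. The double-positive share was 0.685% thinned, 0.943% without list genes and 0.804% to 1.34% leaving out a library, and the proliferating cluster 4.04% to 6.86%. The share of cells with G2 and M phase UMIs, 22.6%, was 12.8% at 5 UMIs and 11.2% thinned, lower by construction. Scaling moved the median of all genes by at most 0.1 except in clusters 6, 7, 8 and 9, where it moved by -0.486 to 0.279.

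Of the summed list levels per library, 307 kept within their counting interval, 174 rose and 95 fell; 94 of the rises came from totals without mitochondrial and ribosomal protein genes, which raise levels by construction. For the knockout comparisons, the other line's wild type, both wild types summed, reweighted shares, variable genes chosen by knockout and other gene-count thresholds were not run, since no library has a genotype. No paired analysis was possible because the groups share only 1 replicate number and the columns carry none. Depth limits low genes such as Il15 (16 UMIs).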

Other observations

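The test of the low-UMI cluster as the source of the Il2ra spread and the Malat1 test were set before their values were seen; all other tests in this part were chosen only after the result was seen. Because no label ties a library to a genotype, no biological explanation was tested for any pattern.

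Across the 4 unassigned libraries, Il2ra was at 181, 181, 31.1 and 158 CPM in libraries 1 to 4, Socs2 at 32.3, 43.8, 0.874 and 39.5 CPM, Capg, an actin-capping protein, at 216, 262, 76.8 and 201 CPM, and Il2rb at 191, 233, 130 and 192 CPM. Il2rg was at 255, 236, 380 and 293 CPM, and Ly6c1 at 9.51, 7.01, 45.8 and 17.1 CPM. Bcl2 stayed between 562 and 638 CPM. The IL-7 receptor gene Il7r was at 56.7, 54.3, 56.5 and 28.5 CPM, and Igfbp4 at 44.4, 105, 33.1 and 44.6 CPM. These genes were picked from the fixed lists after their values were seen. Their levels are whole-library values, not adjusted for cluster shares. In library 3, Il2rb was above the other libraries within clusters 1, 2 and 3 (126, 575 and 139 CPM). Within clusters 4 and 5 it was below them (56.1 and 118 CPM). Bcl2 of library 3 lay within their range in clusters 1 and 2 and below it in clusters 3, 4 and 5 (386, 211 and 118 CPM).

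Summed over lists, genes induced by IL-2 and STAT5 were at 4347, 5059, 3642 and 4707 CPM in libraries 1 to 4, Treg identity genes at 4547, 5077, 3403 and 4633 CPM, and MYC target genes at 6497, 7022, 4663 and 6211 CPM. S phase genes were at 1426, 1631, 608.3 and 1382 CPM, interferon response genes at 4860, 4897, 6411 and 5922 CPM, and TCR and NF-kB response genes at 2325, 2301, 2748 and 2336 CPM. Egress genes were at 15310, 16660, 19630 and 17100 CPM and effector Treg genes at 422, 429.6, 355.6 and 421.1 CPM. Apoptosis regulators ranged from 1592 to 1636 CPM, cytokine receptor genes from 1457 to 1521 CPM and early stress genes from 4831 to 5352 CPM. Oxidative phosphorylation genes lay between 9225 and 10600 CPM, and mitochondrial transcripts between 23370 and 24440 CPM. G2 and M phase genes were at 2166, 2439, 458.9 and 1940 CPM, and immature thymocyte genes were at 1505, 1438, 2494 and 1659 CPM. B cell markers were at 75.1 to 138.5 CPM, myeloid markers at 117.9 to 147.4 CPM, thymic epithelial markers at 15.21 to 19.06 CPM, and innate lymphocyte markers at 277.2, 233.8, 63.66 and 182.4 CPM. Conventional CD4 markers were at 1230 to 1647 CPM. Erythroid markers gave 10732 UMIs in library 3, where 1 cell held 10398 haemoglobin UMIs, and 0, 70 and 11 UMIs in the other libraries. Genes of the sort gate summed to 398.2 to 503.1 CPM. The sex-linked list, nearly all Xist, summed to 1079 to 1193 CPM.

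Technical explanations for the spread of Il2ra, highest to lowest library 5.82 (95% counting interval 4.98 to 6.80), were weighed first. With every cell thinned to 1811 UMIs the spread was 5.68 (4.58 to 7.05). CPM are already divided by total UMIs, so thinning could hardly move them, and this value cannot decide about depth per cell. The low-UMI cluster 7 held 54 Il2ra UMIs, 1 of them in library 3, and 381841 of 33232250 UMIs in all. These are too few to produce the spread, so leaving the cluster out could hardly change it (5.66, 4.85 to 6.60). Different shares of the clusters were not the whole of it: with the 6 clusters that had 20 or more cells in each library weighted by their pooled shares in all libraries, the spread was 2.80 (2.04 to 3.83). It was 4 (3.07 to 5.20) with each of these clusters weighted alike. That value leans on cluster 7, at 427 CPM in library 1 and 5.52 CPM (1 UMI) in library 3. Within clusters 1 to 4 the spread was 2.45 to 2.79, and within cluster 5 it was 5.43 with 6 UMIs in library 3. With pooled shares of clusters made without list genes the spread was 5.35 (4.47 to 6.41). Finer states within clusters, a batch of animals or sorting and genotype stay open and untested.

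Cluster 5 contained transcripts usually described from other tissues. Actg2, smooth muscle actin, was at 169 against 31.1 CPM (4.72-fold, 4.28 to 5.21) and Nefh, a neurofilament subunit, at 27.7 against 7.13 CPM. Further genes, named after their values were seen, were Tff1 (16.3 against 1.23 CPM), thyroglobulin Tg (20.8 against 5.62 CPM), Ddc and Agr3, and all 6 were higher in each of the 4 libraries. RNA from thymic epithelial cells, which the sort gate should remove, is a candidate source and stays open. Epcam was at 23 against 13.9 CPM (log2 ratio 0.78, 0.45 to 1.11), and the other epithelial markers gave only 3 UMIs in cluster 5 and 60 elsewhere, a ratio of 0.395 (0.136 to 1.14) on too few counts to decide. Reads shared between actin genes would keep Actg2 in 1 ratio to Actb and Actg1, and that ratio was 84.3 times as high in cluster 5 as in cluster 1 (49.0 to 159). Cluster 1, the comparator, held 13 Actg2 UMIs; Actg2 was 1.88% of the Actb and Actg1 UMIs in cluster 5 and 0.374% in all other cells. In cluster 5, 10 cells held 97% of the Tff1 UMIs. UMIs of both genes also occurred outside it, in 22 cells for Tff1 and 343 for Actg2, and the level of free RNA was not measured.

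Cluster 7 may hold cells that lost cytoplasm before capture: Malat1, an RNA kept in the nucleus, was at least 2.21 times as high there as in other cells in each of the 4 libraries (highest 2.29), as such cells would show. Malat1 was not barred from the clustering, so it may have helped to form this cluster. Its level in the other cells also differed by library, at 17770, 17050, 33220 and 24110 CPM in libraries 1 to 4. Droplets with free RNA only stay open: mitochondrial transcripts were 2.23 to 3.09 times as high as in other cells, but the profile of free RNA was not measured. The share of cluster 7 was 2.05%, 1.31%, 7.22% and 1.24% in libraries 1 to 4.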
